A study of Sinibotia superciliaris with 2 samples.

How the data were processed

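RNA of black and of yellow skin of Sinibotia superciliaris was sequenced, with 1 library per colour. Per the labels, RNA was extracted with Trizol and libraries followed standard Illumina protocols; per the submitters' processing notes the zebrafish build GRCz11 was used, in a role the notes do not give. The assembler, aligner, counter and database versions are not given in the sources used here, and no genome of this fish was used here. The authors deposited 1 normalised expression signal per unigene and library, in RPM (reads scaled to a library of 1000000 reads). This unit was read from the values, since the file headers do not name it. A unigene appears once per predicted protein, so 4131 of 128781 rows repeated a unigene with the same value, and each of the 124650 unigenes was used once. Counted once, the deposited signal summed to 999612 RPM in the black and 999622 in the yellow library. The deposited annotation table, whose entries are other than measurements (protein matches and GO terms per the file headers), was used for names only.

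The design, fixed before the data were examined, assumed counts or FPKM, RPKM or TPM. The files hold RPM, so the branch for normalised values was kept: log2(value + 1), no further scaling, and a mean of at least 1 RPM over both libraries. For counts the design had fixed TMM scaling, a minimum of summed reads and an interval of each ratio. Since whole reads could be recovered, that branch could also have applied. TMM scaling is given below as an alternative. Whole reads were recovered from the steps between values. 1 read was worth 0.0282 RPM in the black and 0.0261 in the yellow library, and unigenes with 0 reads carry the lowest value in place of 0. With that lowest value, which is 0.5 of a read, taken as 0 reads, 100% of the 124650 black and 99.999198% of the 124650 yellow values were whole within a tolerance of 0.1 read. The recovered totals were 35386871 and 38323075 reads, and 5197 and 6070 unigenes had 0 reads. If reads are taken singly, a count of 0 allows up to 3 reads, or 0.0847 and 0.0782 RPM. Counted in pairs, as for the intervals below, this bound would be higher. Even read numbers were commoner than their odd neighbours at most of the lowest values. In the black library 8897 unigenes had 2 reads against 6459 with 1 and 7299 with 3, and in the yellow library 9992 against 7308 and 8014. The exception up to 6 reads was the yellow library, where 6722 unigenes had 6 reads against 7089 with 5. Mates of a pair thus appear to have been counted separately. The intervals therefore count each pair once. They have the Clopper-Pearson form, conditional on the sum of both libraries, at 95% and cover counting error only. An odd read number enters with a part of a pair, so the intervals are approximate, most so at low read numbers.

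Unigenes were joined into genes by the best Swiss-Prot BLASTX entry name, or BLASTP where there was none, and summed. A symbol with several entry names was summed over them. The annotation used covers 4.55% of the unigenes and its last record breaks off within a description, so it may be a part of a longer table, and a gene it does not name was not analysed here. A unigene or gene was called when it differed at least 2-fold on the log2(value + 1) scale. With 1 library per colour there is no test across fish, no p-value for any gene and no standard error. Because whole reads could be recovered, a count-based rule was added after seeing the data: an interval of the ratio wholly beyond 2-fold. It called 195 unigenes and 26 genes. For 20 gene lists fixed before the data were examined, the median log2 ratio was set against 10000 random lists of the same size matched on deciles of mean expression, and its percentile describes these libraries only. Lists with fewer than 3 measured members were given no median. GO terms with 10 to 500 background genes were tested with a two-sided Fisher's exact test over genes and Benjamini-Hochberg adjustment, with the measured annotated genes as background.

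Named genes followed a fixed rule. It took up to 2 measured members with the largest absolute log2 ratio per list, and up to 4 from the melanin, melanophore, xanthophore and iridophore lists. It always took 20 pigment genes where annotated (9 were and 11 were not), the 5 highest and the 5 lowest ratios at a mean of at least 10, and the 3 most abundant genes per library. Together this named 60 genes. Alternatives were TMM and median-of-ratios scaling, pseudocounts of 0.1 and 5, no or a 5 times higher minimum, a 4-fold rule, other ways of joining unigenes, unmatched random lists, and totals without the 100 most abundant unigenes. Added after seeing the data were the interval rule, totals without the 2 most abundant unigenes, and the totals without 100 for genes. After seeing the data, 3 further marker lists (oocyte and germ cell, fast muscle, slow and cardiac muscle) were written for the closing observations.

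The steps were tested on simulated data with 200 changed features, drawn from the real means and library sizes. For genes, run on 4058, the size rule called 0 of 3446 unchanged genes, 0 of 50 changed 1.5-fold and 50 of 50 changed 3-fold. For unigenes, run on 124650, it called 0 of 31727 unchanged, 36 of 50 changed 3-fold and 49 of 50 changed 6-fold. The intervals held the true ratio for 95.4% of genes and 95.8% of unigenes. That simulation contains counting noise only, not differences between fish. Its counts were drawn as whole read pairs from the model that the intervals assume, so coverage near 95% followed from its design. It held no odd read numbers and no shift of composition between the libraries. Of 100 random lists of 10 genes, 4 fell outside the middle 95%. These lists were drawn from the real log2 ratios and set against draws from the same genes, so a count near this was fixed in advance. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16, the last only for TMM factors on the recovered reads.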

Results

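Skin of Sinibotia superciliaris (also called Botia superciliaris), a loach with a striped skin pattern, was profiled by RNA sequencing to compare transcript levels between its black and its yellow skin. According to the labels the fish were wild adults weighing 6.25 ± 0.30 g and measuring 8.75 ± 0.20 cm, and skin of both colours came from 6 individuals. The labels do not say what the ± values stand for, or whether RNA of the 6 fish was pooled. There was 1 library of black skin and 1 of yellow skin, so no difference below has a replicate check, and every comparison is between these libraries only. The black library held 35386871 reads and the yellow library 38323075 reads, spread over 124650 unigenes (the gene identifiers of the files). The deposited annotation gave protein matches for 5676 of these unigenes, which held 20.6% of the black and 17.8% of the yellow reads. The matches grouped into 4058 genes. Genes are named here by their best protein match, which does not establish orthology and cannot separate near-identical copies. Levels are in RPM, the reads of a gene scaled to a library of 1000000 reads. Ratios of RPM carry approximate 95% intervals that cover counting error only, with each read pair counted once. Whether PCR copies were removed is not stated, and the intervals do not allow for them. Log2 ratios are black over yellow on the log2(value + 1) scale, which understates differences of low genes.

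The black library carried far more melanin-pathway RNA, while most annotated genes differed little between the libraries. Of 3644 genes past the abundance minimum, 30 were at least 2-fold higher in the black library and 5 at least 2-fold higher in the yellow library. The log2 ratio of these genes had a median of 0.21 and a standard deviation of 0.30 across genes, so a log2 ratio near 0.21 marks a gene that sat with the bulk. The 5 genes higher in yellow skin were APOD (apolipoprotein D), APRT (adenine phosphoribosyltransferase of purine salvage), CYP24A1 (a vitamin D hydroxylase, Swiss-Prot entry CP24A), CAHZ (a fish carbonic anhydrase) and EPHX3 (an epoxide hydrolase). APOD and CYP24A1 fell outside the rule for named genes and were chosen after their values were seen. Among all unigenes, 31795 passed the minimum, 249 were at least 2-fold higher in the black library and 96 in the yellow library, with a median log2 ratio of 0.14. The split depended on scaling. After TMM scaling it was 129 against 172 unigenes and 22 against 7 genes. The design had fixed this scaling for counts, and it shifted the log2 ratios by 0.19. That scaling applies 1 factor to all genes of a library. It put the medians of the xanthophore, iridophore, stripe, nerve, vessel and fat, stress and clock lists below 0, and none of these was then in the outer 5% of random lists. Median-of-ratios scaling gave 143 against 152 unigenes. Without the 2 most abundant unigenes, an alternative chosen after seeing the data, it was 174 against 190 unigenes and 24 against 9 genes. Without the 100 most abundant unigenes it was 280 against 356 unigenes and 29 against 13 genes, the gene value again chosen after seeing the data. The 2 most abundant unigenes, c33693_g2 and c124000_g1, have no protein match in the annotation used here. They held 6.81% of the black and 17.0% of the yellow reads.

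**Figure D1:**
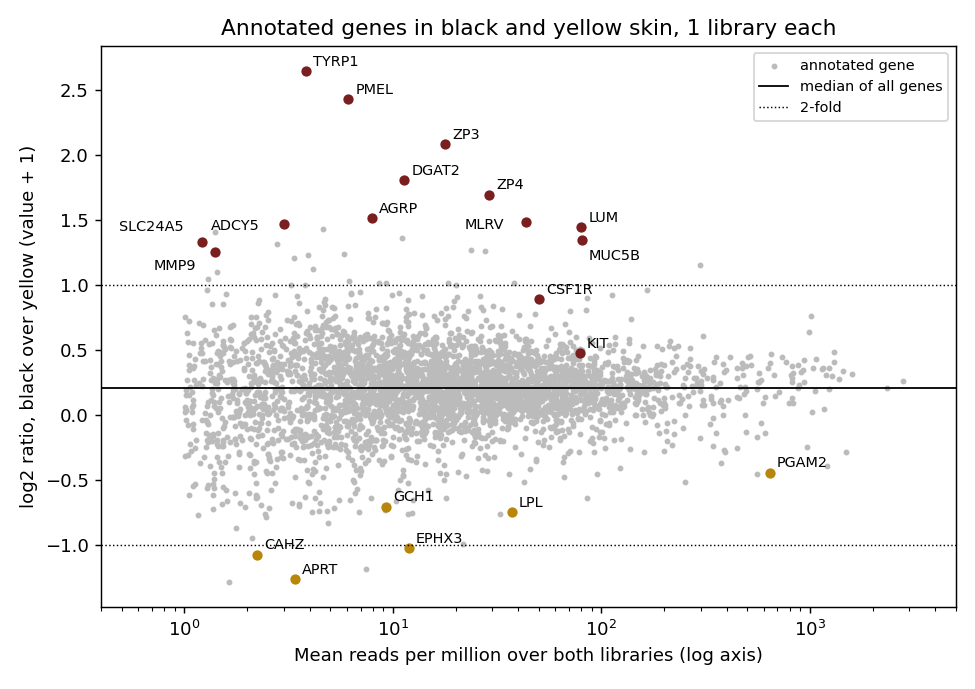
Log2 ratio of black over yellow skin (RPM + 1) against the mean RPM (log axis) for the 3644 annotated genes past the minimum, 1 library per colour. Dark red marks named genes above the median of 0.21 (solid line) and ochre marks named genes below it; TYRP1 at 2.64 and PMEL at 2.43 lie farthest above the dotted 2-fold lines.

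Melanin synthesis showed the widest gap between black and yellow skin. TYRP1, an enzyme of eumelanin synthesis, was at 7.34 RPM in the black and 0.339 in the yellow library, a ratio of 21.7 (interval 9.96 to 57.3). PMEL, which forms the fibrils on which melanin is laid down, was 8.94-fold higher in the black library (5.81 to 14.4). SLC24A5, an ion exchanger of pigment organelles, was 8.34-fold higher (3.28 to 27.1). Tyrosinase (TYR), the enzyme of the rate-limiting step, was below the abundance minimum, with 37 black reads and 5 yellow reads and a ratio of 8.01 (2.16 to 52.2). These 4 genes were the unigenes c108141_g3, c92947_g1, c139776_g1 and c73690_g1. Of the 14 genes fixed for this list, 4 were annotated and 3 measured past the minimum. All 3 were at least 2-fold higher in the black library, and their median log2 ratio of 2.43 lay at percentile 100 of random lists of the same size and expression. DCT, SLC45A2, OCA2 and MLANA were not analysed here because the annotation used did not name them. Genes of melanosome biogenesis and transport past the minimum sat with the bulk as a list. None of the 8 measured members passed 2-fold, their median log2 ratio was 0.22 (percentile 54.35), and the largest log2 ratios among these were those of ATP6AP1, a proton pump subunit, at 0.42 and of MYO5A, a motor that carries melanosomes, at 0.35. RAB38, a small GTPase of melanosome cargo transport named after its values were seen, was below the minimum like TYR, with 44 black and 7 yellow reads and a ratio of 6.81 (2.19 to 30.5).

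The measured regulators of melanophores and neural crest cells were also higher in the black library as a list. Of the 24 genes fixed for this list, 7 were annotated. All 7 were measured, 2 were past 2-fold, and the median log2 ratio was 0.50 (percentile 99.43). That median is the value of MCHR1, which rested on 71 black and 43 yellow reads. AGRP, whose closest database match is the fish agouti-related protein 2, a secreted antagonist of melanocortin receptors, was at 12.3 RPM in black and 3.65 in yellow skin, a ratio of 3.36 (2.55 to 4.46). Its log2 ratio was 1.51 from the sum of its unigenes and 1.07 from the most abundant of them, and it had no value at a BLASTX E-value of 1e-20 or lower. ADCY5, an adenylate cyclase that makes cAMP, was 4.33-fold higher in the black library (2.68 to 7.31), and its log2 ratio of 1.47 was 0.68 when unigenes were grouped by BLASTP hit. ERBB3, a receptor needed by pigment cell progenitors, had a ratio of 1.44 (1.38 to 1.52), and MCHR1, a melanin-concentrating hormone receptor, one of 1.79 (1.02 to 3.21). KIT, a receptor that melanophores need to migrate and survive, was at 91.6 and 65.7 RPM in black and yellow skin, a ratio of 1.39 (1.29 to 1.50). MITF, SOX10, MC1R and ASIP were not analysed here for lack of an annotated unigene.

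The measured xanthophore genes, which serve the yellow pigment cells, did not stand apart as a list. Of the 26 genes fixed for this list, 10 were annotated, and the others, XDH among them, were not analysed here. None of the 10 measured members passed 2-fold, and the median log2 ratio was 0.12 (percentile 15.55). Members went both ways. GCH1, which starts pteridine synthesis, was the member most on the yellow side, at 6.78 RPM in black and 11.7 in yellow skin, a yellow over black ratio of 1.72 (1.37 to 2.17). CSF1R, the receptor that xanthophores require and that macrophages also carry, was instead 1.87-fold higher in the black library (1.70 to 2.06). SCARB1, which takes up carotenoids, was 1.81-fold higher in black (1.28 to 2.58). QDPR, which recycles tetrahydrobiopterin, had a black over yellow ratio of 1.29 (1.07 to 1.55). BCO2, which cleaves carotenoids, had a ratio of 1.28, with an interval of 0.995 to 1.65 that includes no difference.

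Iridophore and purine synthesis genes also sat with the bulk, with a median log2 ratio of 0.18 over 13 measured members (percentile 33.85). With the most abundant unigene of each gene in place of the sum, the percentile was 1.98. APRT was the single member past 2-fold, at 1.58 RPM in black and 5.19 in yellow skin, a yellow over black ratio of 3.28 (2.14 to 5.19); its closest database match is an uncharacterised protein. GMPS and PPAT, both enzymes of purine synthesis, were on the black side with ratios of 1.80 (1.47 to 2.20) and 1.80 (1.40 to 2.31), and PAICS had a ratio of 1.35 (1.23 to 1.49). Of the 22 genes fixed for the iridophore list, 13 were annotated, and LTK and PNP were among those not analysed here. Of 8 measured stripe pattern genes, none passed 2-fold on the log2(value + 1) scale, and the list median was 0.16 (percentile 24.58). GJA5, whose closest match is connexin 41.8, the gap junction protein of the zebrafish leopard mutant, had a log2 ratio of 0.86 and a black over yellow ratio of 2.18 (1.49 to 3.22). AQP3, a water and glycerol channel, was abundant in both libraries with a ratio of 1.19 (1.17 to 1.22).

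**Figure D2:**
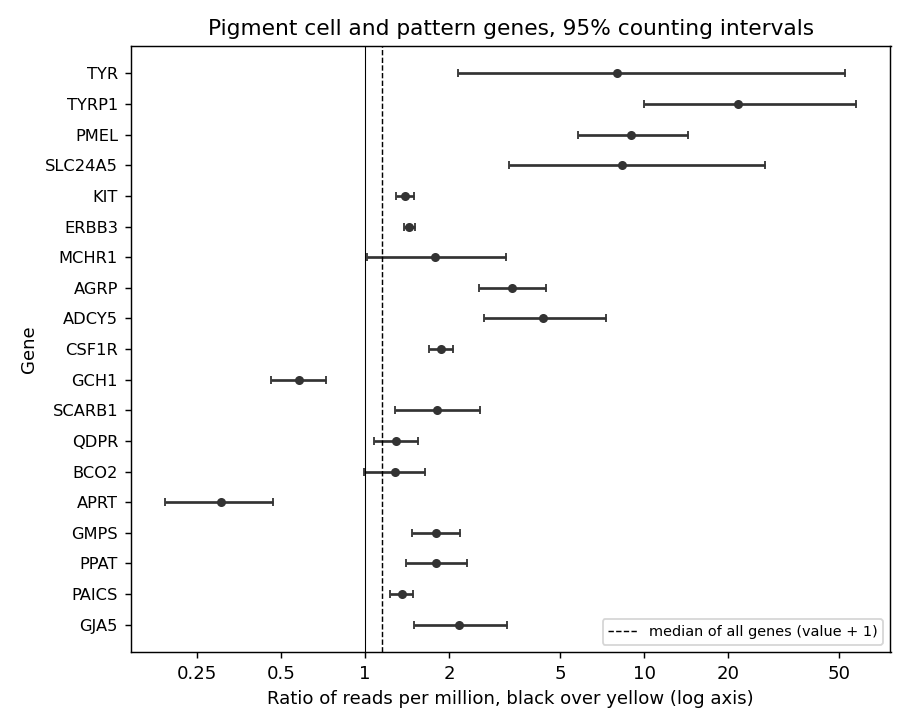
Black over yellow ratio of RPM (log axis) for named pigment cell and pattern genes, 1 library per colour, with 95% counting intervals as bars. The solid line marks equal levels and the dashed line the median of all genes. TYRP1 at 21.7, PMEL at 8.94, SLC24A5 at 8.34 and TYR at 8.01 lie to the right, while GCH1 and APRT lie left of equal levels.

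Among signalling lists, the Wnt median lay in the outer 5% of random lists and the MAPK and cAMP median did not; the lists were not tested against each other. The 20 measured Wnt genes had a median log2 ratio of 0.36 (percentile 97.94), with 1 past 2-fold. SFRP1, a secreted Wnt antagonist, was 2.21-fold higher in the black library (1.74 to 2.82), and FZD1, a Wnt receptor, 1.99-fold higher (1.46 to 2.72). The log2 ratio of FZD1 was 0.82 from the sum of its unigenes and 0.20 from the most abundant of them. SFRP1 was no longer past 2-fold with TMM scaling, at 0.85. The Wnt percentile left the outer 5% under 4 alternatives. The 20 measured MAPK and cAMP genes had a median of 0.21 (percentile 52.325) and none past 2-fold on the log2(value + 1) scale. GNAI2, an inhibitory G protein subunit, had a log2 ratio of 0.93 and an RPM ratio of 2.12 (1.60 to 2.83). DUSP6, a phosphatase that dampens ERK, had a log2 ratio of 0.58.

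Markers of other cell types differed between the libraries as well. Immune cell markers were on the black side, with a median log2 ratio of 0.58 over 7 measured genes (percentile 99.98) and none past 2-fold. Of the 30 genes fixed for this list, 9 were annotated, and 6 of the 7 measured lay above the median of all genes. The T cell kinase LCK had a ratio of 1.72 (1.37 to 2.17) and the chemokine receptor CXCR4 one of 1.67 (1.36 to 2.06). Dermal matrix and scale markers had a median of 0.36 over 16 genes (percentile 98.96, and 97.295 without the 100 most abundant unigenes), and 2 passed 2-fold. LUM, the collagen-binding proteoglycan lumican, was at 117 RPM in black and 42.6 in yellow skin, a ratio of 2.76 (2.54 to 2.99). The matrix protease MMP9 was 5.69-fold higher in black (2.64 to 14.0). The 3 measured mucous cell markers had a median of 0.44 (percentile 95.69), led by MUC5B, whose closest match is mucin-2, with a ratio of 2.57 (2.37 to 2.79), and by the glycosyltransferase GALNT7 at 1.36 (1.26 to 1.47). The measured keratinocyte markers, with a median of 0.26 over 8 genes (percentile 75), sat with the bulk. Of the 27 fixed for this list, 8 were annotated and none of these was a keratin. The desmosome genes DSG2 and DSP had ratios of 1.44 (1.38 to 1.51) and 1.26 (1.21 to 1.31).

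Skeletal muscle markers were on the yellow side, with a median log2 ratio of -0.14 over 16 measured genes (percentile 0). Of these, 4 lay above 0, and the mean was -0.01. PGAM2, a glycolytic enzyme of muscle, was at 543 RPM in black and 740 in yellow skin, a yellow over black ratio of 1.36 (1.33 to 1.40). ATP2A1, by contrast, was 2.49-fold higher in the black library (2.17 to 2.86); its closest match in the other database is a different calcium pump, SERCA3. Of 3 measured blood cell markers (median -0.20, percentile 2.295), CAHZ had a yellow over black ratio of 3.13 (1.86 to 5.54) and TFR1, the transferrin receptor, a log2 ratio of 0.43. The blood percentile left the outer 5% with a pseudocount of 0.1 (2.62) and with the most abundant unigene (2.625), and had no value at 5 times the minimum. Vessel and fat markers had a median of 0.06 over 9 genes (percentile 6.265), with percentiles of 0.25 at 5 times the minimum and 29.33 with no minimum. DGAT2, which makes triglycerides, was 4.05-fold higher in black (3.18 to 5.20), while LPL, a lipoprotein lipase, had a yellow over black ratio of 1.70 (1.52 to 1.91). The 4 measured nerve and glia markers had a median of 0.02 (percentile 16.21); SOX2 had a log2 ratio of -0.35 and PMP22 one of 0.23.

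Cell cycle genes had a median log2 ratio of 0.41 over 13 genes (percentile 98.465), and 1 passed 2-fold. CCNA2, cyclin A2, was 2.32-fold higher in the black library (1.74 to 3.11) and the mitotic motor KIF11 1.80-fold higher (1.40 to 2.31). CCNA2 was no longer past 2-fold with TMM scaling, at a log2 ratio of 0.87. The percentile of this list left the outer 5% under 4 alternatives. Stress and immediate early genes had a median of 0.18 over 8 genes (percentile 32.62). HSP90AA1, a chaperone, had a log2 ratio of 0.58 and EGR1, an early response transcription factor, one of 0.40. The 4 circadian clock genes had a median of 0.15 (percentile 34.89), with CRY2 at 0.21 and PER1 at 0.20. Of the mitochondrially encoded genes, 1 was annotated and none was past the minimum.

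**Figure D3:**
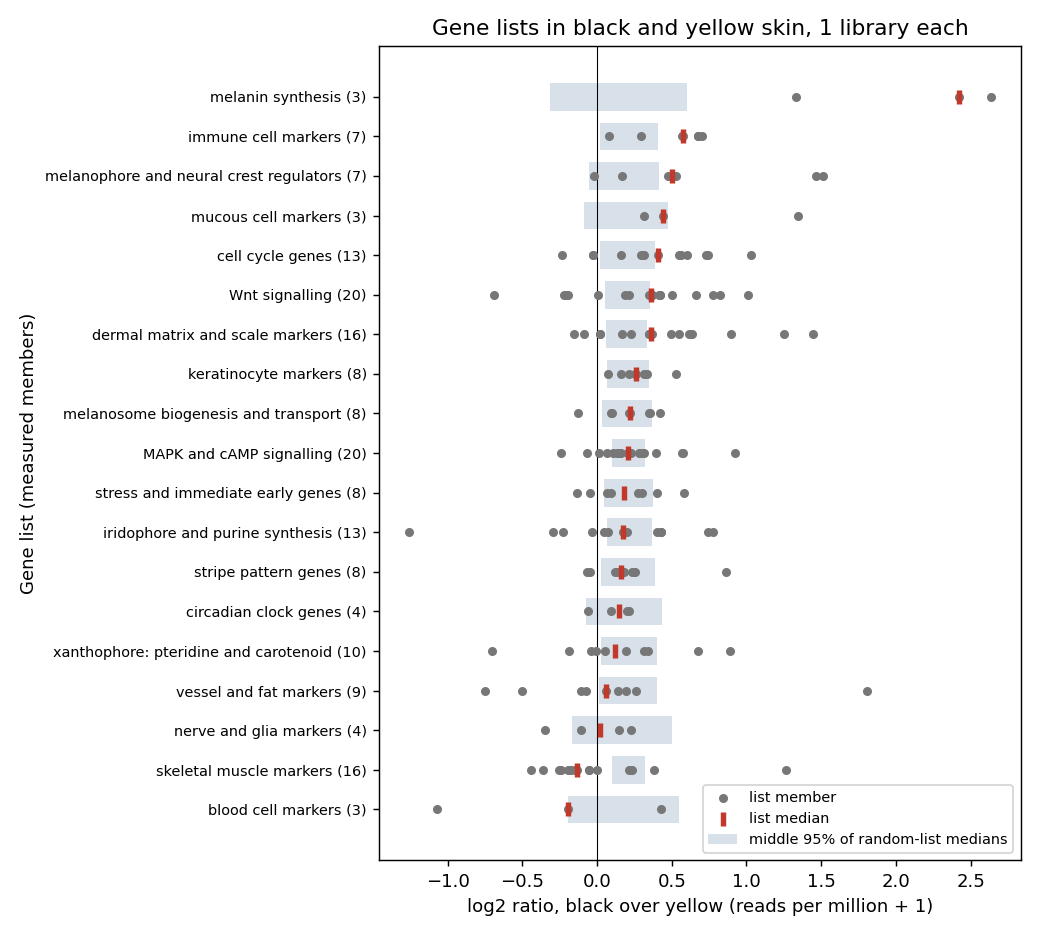
Log2 ratio of black over yellow skin for the measured members (grey points) and the median (red bar) of each gene list, 1 library per colour, against the middle 95% of medians of 10000 random lists matched on expression (pale band). The melanin median of 2.43 lies beyond its band and the skeletal muscle median of -0.14 lies below its band.

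Across all annotated genes, those with the highest ratios at a mean of at least 10 RPM were ZP3, DGAT2, ZP4, MLRV and LUM. ZP3 and ZP4 encode egg-envelope glycoproteins. ZP3 was at 29.3 RPM in black and 6.16 in yellow skin, a ratio of 4.76 (3.89 to 5.86), and ZP4, whose closest match is carp ZP2, had a ratio of 3.40 (2.95 to 3.93). MLRV, a regulatory myosin light chain of ventricle and slow muscle, had a ratio of 2.88 (2.57 to 3.22). At the yellow end were EPHX3 with a yellow over black ratio of 2.17 (1.77 to 2.68) but no value when unigenes were grouped by BLASTP hit, ASB2, a ubiquitin ligase subunit of muscle and blood cells, with 2.06 (1.77 to 2.40), and CLDY, a claudin, with 1.73 (1.53 to 1.95). MYLK3, a myosin light chain kinase, and ECI1, an enzyme of fatty acid oxidation, each had a yellow over black ratio of 1.77. The most abundant annotated genes were APOEB, an apolipoprotein, at 3044 and 2536 RPM in black and yellow skin, and MYH9, non-muscle myosin, at 2516 and 2178. They were followed by RL7A in the black library and by the glycolytic enzyme ALDOA, at 1339 and 1636, in the yellow library. The GO test rested on only 28 called genes for black and 5 for yellow. Of 416 terms tested per direction with Fisher's exact test over genes, 0 passed an adjusted p of 0.05, the lowest adjusted p was 0.908, and 8 terms for black and 7 for yellow had an unadjusted p under 0.05. That test describes genes of these libraries, not fish.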

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

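The interval rule, the totals without the 2 most abundant unigenes and, for genes, the totals without the 100 most abundant were chosen after seeing the data; the other alternatives were planned. Counts of unigenes at least 2-fold apart (345 together) were 1411 with a pseudocount of 0.1, 53 with 5, 140 at 5 times the minimum, 13 at 4-fold, 636 without the 100 most abundant unigenes and 195 with the interval rule. Counts of genes (35 together) were 86 with a pseudocount of 0.1, 11 with 5, 20 at 5 times the minimum and 3 at 4-fold. A lower pseudocount lets more low unigenes pass by construction, and a stricter rule or minimum fewer. Leaving out the 100 most abundant unigenes raises all remaining values against the fixed minimum and pseudocount; how much of the higher count this explains was not tested. The melanin median was 3.06 with a pseudocount of 0.1 and 1.21 with 5, and at 5 times the minimum too few members were left for a value. Its percentile was at least 99.995 under every alternative that gave one. Of 19 list medians, 8 lay outside the middle 95% of random lists, against 5 of 16 at 5 times the minimum and 5 of 19 without the 100 most abundant unigenes. At 5 times the minimum the melanin, blood and nerve lists had too few members for a value, the Wnt and cell cycle lists left and the vessel and fat list entered. Why lists with a value moved was not tested. Immune, melanophore and skeletal muscle lists stayed outside under every alternative. With a pseudocount of 5, SLC24A5, AGRP, ADCY5, APRT, SFRP1, CAHZ, MMP9, CCNA2 and EPHX3 were no longer 2-fold apart, since a pseudocount shrinks the ratios of low genes. GO terms past the threshold were also 0 with the 4-fold rule and at 5 times the minimum, but with at most 3 and 20 called genes these decide little. Over all alternatives no called direction reversed, and 25 of 37 counts stayed within 1.5 times the main count. Of 206 list medians under alternatives, 190 stayed within a 95% interval of the main median and 16 moved. That interval was taken from the ranks of the members, and in short lists it spans them all. Of 656 gene values, 512 stayed within counting error and 144 moved. A changed minimum cannot alter a gene value, and taking the most abundant unigene cannot alter a gene with a single unigene. Part of the 512 was thus fixed in advance, and the share does not measure robustness. No paired analysis was possible because each colour has 1 library and no test across samples was made. Depth limits the low genes: TYR rests on 37 and 5 reads, and its interval spans 2.16 to 52.2.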

Other observations

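All tests in this part were chosen after the results were seen. Except for ZP3, ZP4, KIT, ATP2A1 and MYL2, the genes given values here fell outside the rule for named genes, and they were chosen after their values were seen. HMR1, a class I histocompatibility gene, was at 412 RPM in black and 184 in yellow skin, a ratio of 2.23 (2.14 to 2.32). An immunoglobulin mu heavy chain, entry HV303, had a ratio of 3.04 (2.07 to 4.56), and MRC1, the macrophage mannose receptor, one of 2.05 (1.84 to 2.30).

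On the yellow side, APOD had a yellow over black ratio of 5.10 (2.53 to 11.5) on 19 black and 105 yellow reads, and the vitamin D hydroxylase CYP24A1, entry CP24A, one of 2.59 (1.97 to 3.43). Unigene c33693_g2 alone was at 47717 RPM in black and 113645 in yellow skin, a yellow over black ratio of 2.38, and c124000_g1 at 20383 and 55923, a ratio of 2.74. Among unigenes higher in black without a protein match, c104991_g3 had a ratio of 14.9 and c107685_g1 one of 6.82.

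The 4 annotated melanin genes were higher in the black library. The share of yellow reads taken by a few unigenes does not account for this, since after TMM scaling the lowest lower bound of their ratios was still 1.90. Ideal counting noise of read pairs does not either, with a lowest lower bound of 2.16, that of TYR on 37 and 5 reads. At so few reads that interval is approximate, and it does not allow for PCR copies. Whether the black skin held more melanophores or each held more of these transcripts cannot be told apart: KIT, which other cells also use, had a ratio of 1.39, and MITF and SOX10 were not analysed here. A difference between the fish or dissections behind the 1 library per colour stays open as well.

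The egg-envelope genes ZP3 and ZP4 were higher in the black library, and after TMM scaling the lower of their lower bounds was 2.59, so scaling does not account for it. A candidate explanation is ovary RNA in the black library, which cannot be told apart here because only 5 of 30 oocyte and germ cell genes were in the annotation used here and 2 of these were past the minimum. Of these, the germ cell helicase DDX4 was at 6.52 and 4.56 RPM, with a ratio of 1.43 (1.07 to 1.91), and the lipoprotein receptor VLDLR, which other tissues also express, had a log2 ratio of 0.22. The skin's own use of these genes was not tested.

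More muscle tissue in the yellow library may underlie part of the muscle difference. Of 14 measured fast muscle genes, 13 were lower in the black library, with a median log2 ratio of -0.25 (percentile 0). Since 10 of the 14 were already in the fixed skeletal muscle list, only 4 are new, and these were all lower. Among the most abundant, ENO3 was at 891 and 1056 RPM in black and yellow skin. The explanation is at odds with 4 of 24 muscle genes (myosin heavy chains counted as 1) whose intervals stayed above 1 after TMM scaling, namely ACTA1, ATP2A1, MYL4 and MYL2, although ACTA1 can share reads with other actins and ATP2A1 matches another pump. The slow and cardiac list had a median of -0.20 over 7 genes (percentile 0.01) but a mean of 0.21. MYL4 and MYL2 (entry MLRV) were past 2-fold on the black side, while MYBPC1, at a log2 ratio of 0.22, sat with the bulk. A different mix of muscle fibres or cells thus stays open and untested.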
